A study of Escherichia coli with 2 samples.

How the data were processed

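Total RNA of 2 cultures of E. coli BL21(DE3) was sequenced, a control and a culture given 3% ethanol at induction, both sampled at 2 h after induction. Per the labels, RNA was isolated with a column kit, ribosomal RNA was depleted, and libraries were made with a directional (strand-marking) kit. Per the submitters' processing notes, the tools were FastQC, cutadapt, Bowtie2, Bowtie, HTSeq and DESeq, with no versions and no order given. The genome build, the handling of reads that map to several places and the strand setting of the counting are not given in the sources used here.

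The deposited signal values are expression levels per gene and library. Per the file headers, the authors compared the libraries with DESeq and used the control library as the reference. Each deposited signal value was found to be a whole multiple of 1 number per library, 0.577 in the control and 1.73 with ethanol. This held for 62 of 62 control values and 45 of 45 ethanol values (100%, within a relative tolerance of 1e-06). The product of both numbers is 1, as for size factors scaled to the geometric mean of 2 libraries, and their ratio is 3. The deposited values were therefore read as reads per gene divided by the authors' size factors, and reads were recovered by dividing by these numbers. The deposited fold is the ratio of the ethanol value to the control value, and the deposited log2 fold is its logarithm. Both were checked against the levels, with differences of at most 6.0e-15. The deposited p-value and adjusted p-value are those of the authors' test of 1 library against 1. The deposited summary gives numbers of genes per class. Totals per library were not used here, so the depth behind each value is given as reads per gene.

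The design planned before the data were examined foresaw no test over replicates, because each condition has 1 library, and the planned analysis was kept. For each gene the fold was given with an exact 95% interval of the ratio of 2 Poisson counts (conditional binomial, Clopper-Pearson), scaled by the authors' size factors. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 was given an upper limit of 3 counts, which is a level of 1.73 in the control and 5.20 in the ethanol library. No count model was fitted to the recovered reads, since without replicates the spread between cultures cannot be estimated. On Poisson counts simulated for the 43 genes, 95.8% of 6450 intervals held the true fold. Such counts follow the model that the interval assumes, so this checks the calculation only. The simulation held no selection of genes by their fold, so it does not cover intervals of genes listed for being lower.

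In total 27 gene lists with 819 genes were fixed before the data were examined. For each list the number of members among the 43 lower genes was set against 10000 random lists of the same size drawn from the 4381 genes detected in both libraries. This assumes that every listed gene was among those detected. The resulting shares of random lists were not corrected for the number of lists compared, and no random list was matched on expression. The rule for named genes, also fixed beforehand, took the 15 genes with the largest folds among those whose larger value reached the median of the list, the 5 genes with the highest values in each deposited table, and up to 4 members of each fixed list with at least 3 members. It named 18 of the 43 genes. Genes chosen after their values were seen are marked as such.

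Locus tags and annotations are those of the deposited tables, which carry no coordinates. Symbols were taken from the annotation text in those tables for 27 of the 43 rows, and 16 are given by locus tag. Product and protein annotations of several hypothetical proteins name different proteins, so these are not given a function. A gene table of E. coli K-12 MG1655 (assembly ASM584v2), another strain, served only to check symbols (26 of 27 found, and 818 of 819 list genes) and to see which genes are neighbours. The 3 near-identical copies of the insertion element IS186 and overlapping or multicopy tRNA genes can share reads, so their values are uncertain.

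Alternatives planned before the data were examined were scaling to the total of the listed genes, a log2 threshold of -2, minimum values of 10 and 50, pseudocounts of 1 and 10, counting intervals that exclude the threshold, 1 gene counted per run of neighbouring genes, and adding the genes listed for the control library alone. Alternatives added afterwards were a size factor ratio of ethanol over control 10% lower, which raises every log2 fold by 0.15, and counting intervals that exclude no change. Also added were 1 row for the IS186 copies, and leaving out tRNA and hypothetical protein genes. Tables of the genes classed as higher or neutral were not analysed here. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.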

Results

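The transcriptome of Escherichia coli BL21(DE3), a B strain in which a phage T7 RNA polymerase gene under lac control drives recombinant genes, was sequenced while the cells produced an antibody fragment. A control culture in complex medium was compared with a culture in the same medium that received 3% ethanol when expression was induced. RNA was taken 2 h after induction, and 1 library was made per condition. The comparison addressed which transcripts differed when ethanol was added at induction. In the authors' deposited summary, 4381 genes were detected in both libraries, of which 640 were classed as higher with ethanol, 43 as lower and 3698 as neutral. Genes classed as lower were thus 0.982% of those detected in both. A further 19 genes were listed for the control library alone and 2 for the ethanol library alone. The levels of the higher and neutral genes were not analysed here, so the values below cover the 43 lower genes and the 21 genes listed for a single library.

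With no replicate libraries, no difference given here was tested against the spread between cultures. The deposited levels are normalised read counts, and 1 read was worth 0.577 in the control library and 1.73 in the ethanol library. The authors' size factor of the control library was thus 3 times that of the ethanol library. Totals of reads per library were not used here. The 43 lower genes held 749054 reads in the control library and 80575 in the ethanol library. Reads per gene ran from 8 to 277700 in the control (median 255) and from 1 to 29732 with ethanol (median 41). The ranges after each fold are exact 95% intervals from these reads. They cover counting error only and compare the 2 libraries, not the 2 conditions.

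Of the genes lower with ethanol, the glycerol-3-phosphate dehydrogenase gene glpD had the largest fold. Heat shock chaperone genes formed the largest group from any of the fixed gene lists. The level of glpD, which encodes the aerobic glycerol-3-phosphate dehydrogenase, was 14871 in the control library and 1670 in the ethanol library, 8.91 times lower (8.35 to 9.51). Transcripts of dnaK, the Hsp70 chaperone, were 3.64 times lower (3.58 to 3.70), and those of ompA, a major outer membrane protein and the most abundant of the 43, were 3.11 times lower (3.08 to 3.15). The median over the 43 genes was 2.39 times lower (log2 fold -1.26), and the log2 folds ran from -3.15 to -1.01. The counting interval lay wholly beyond 2 times lower for 16 genes and reached that value for the other 27. It reached no change for 6 genes. The 43 genes were classed by their folds in these same reads, and the intervals are not corrected for that selection. Intervals clear of no change are thus in part a result of the selection. The count of 43 depends on the scaling and the low genes. With a size factor ratio of ethanol over control 10% smaller, an alternative added after the values were seen, 26 genes stayed beyond 2 times lower. With a pseudocount of 10, 22 genes did. When scaled to the total of the 43 genes, a total of genes selected for being lower, 1 did.

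**Figure D1:**
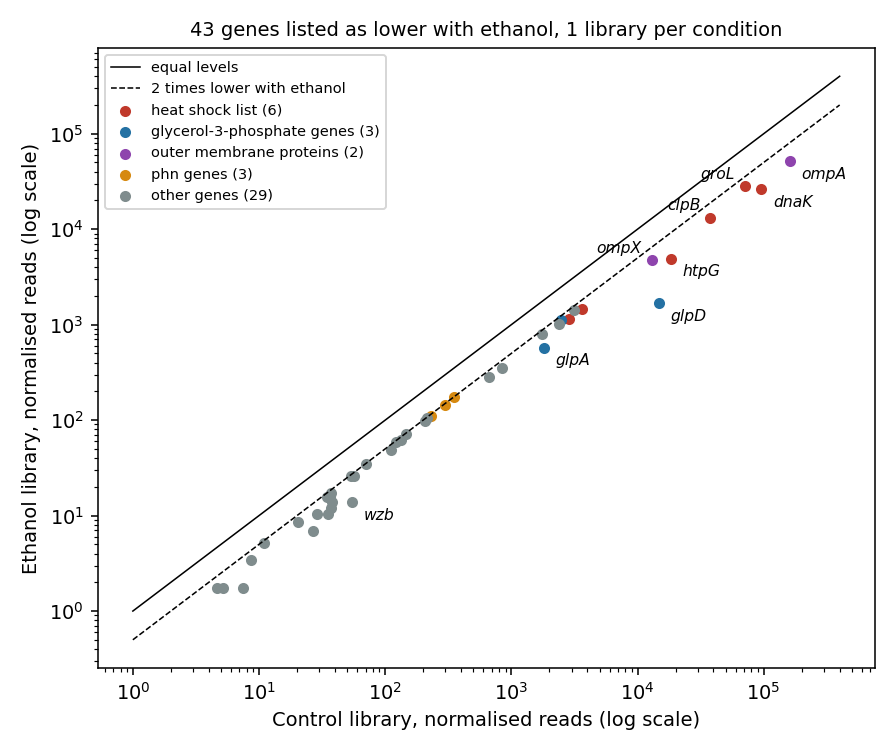
Normalised reads of the 43 genes classed as lower, in the control library (horizontal, log scale) and the ethanol library (vertical, log scale), 1 point per gene. The solid line marks equal levels and the dashed line 2 times lower, and glpD lies farthest below the dashed line among the abundant genes, at 14871 in the control and 1670 with ethanol.

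The list of heat shock chaperones and proteases, drawn up around the heat shock sigma factor RpoH, held 18 genes including rpoH itself. Of these, 6 were among the 43. They were htpG, dnaK, clpB, groL, ibpA and dnaJ, and all 6 encode chaperones. The Hsp90 homologue htpG had a level of 18416 in the control and 4909 with ethanol, 3.75 times lower (3.61 to 3.90). The level of dnaK was 95666 in the control and 26291 with ethanol. The disaggregase gene clpB was 2.89 times lower (2.82 to 2.96), with levels of 37864 and 13089. The chaperonin gene groL was 2.51 times lower (2.47 to 2.55), with levels of 70502 and 28109. The small heat shock protein gene ibpA and the DnaK cochaperone gene dnaJ were each 2.50 times lower (2.31 to 2.72 and 2.32 to 2.69). The median of the 6 genes was 2.70 times lower, against 2.33 for the other 37 of the 43 genes. The summed level of the 6 was 228943 in the control library and 74996 in the ethanol library. The other 12 genes of the list, which include the chaperone genes groS, grpE and ibpB and the protease genes lon and clpP, were not among the 43. A random list of 18 genes would hold 0.177 of the 43 on average, and 0 of 10000 random lists held 6 or more. That count describes these 2 libraries, and the random lists were not matched on expression, because levels of the other genes were not analysed here. The 6 genes share a regulator, and dnaK and dnaJ are neighbours in E. coli K-12. They are thus not independent members, whereas the random lists drew each gene separately. When every level was instead scaled to the total of the 43 genes, which adds 1.63 to every log2 fold by construction because these genes were selected for being lower, 0 of the 6 remained at 2 times lower or beyond, and clpB, groL, ibpA and dnaJ changed direction.

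Genes of glycerol uptake and use belonged to 2 of the fixed lists. Beside glpD, the list of alternative sugar and polyol use had glpF, the glycerol facilitator, with a level of 2452 in the control and 1128 with ethanol, 2.17 times lower (2.00 to 2.37). The list held 94 genes, and 2403 of 10000 random lists of that size held 2 or more of the 43. In the list of anaerobic respiration and fermentation, 2 of 64 genes were among the 43, and 1320 of 10000 random lists held as many. They were glpA, a subunit of the anaerobic glycerol-3-phosphate dehydrogenase, at 3.16 times lower (2.82 to 3.55), and hypA, a hydrogenase maturation factor, at 2.02 times lower (1.53 to 2.69). The other glp genes of these lists, namely glpB, glpC, glpK, glpT, glpQ and glpX, were not among the 43. The gene hypA lies outside the rule for named genes and was chosen after its values were seen.

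Among porins and abundant outer membrane proteins, 2 of 14 listed genes were lower, and 75 of 10000 random lists held as many. This share was not corrected for the 27 lists compared, and the random lists were not matched on expression. The level of ompA was 160330 in the control and 51497 with ethanol. The level of ompX, a small outer membrane beta-barrel protein, was 12907 and 4715, 2.74 times lower (2.63 to 2.85). The porin genes ompC and ompF and the lipoprotein gene lpp were not among the 43.

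Of 29 genes in the phosphate starvation list, 3 were among the 43, and 27 of 10000 random lists held as many. All 3 belong to the phosphonate uptake and carbon-phosphorus lyase genes, which lie within 9 genes of each other in E. coli K-12, so they are not independent members. Their share of random lists was likewise not corrected for the number of lists compared. The level of phnH was 230.4 in the control and 110.9 with ethanol, 2.08 times lower (1.59 to 2.75). Transcripts of phnC were 2.06 times lower (1.64 to 2.63) and those of phnL 2.02 times lower (1.63 to 2.51). Each of these intervals reached 2 times lower. With a size factor ratio of ethanol over control 10% smaller, an alternative added after the values were seen, 0 of the 3 genes stayed at that threshold. The phosphate sensing and uptake genes phoB, phoR and pstS were not among the 43.

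The other 22 fixed lists had no gene among the 43. They cover envelope stress, phage shock, osmotic stress, acid resistance and general stress, oxidative stress, cold shock, flagella, fimbriae, ribosomal proteins, translation factors, the TCA cycle, glycolysis, aerobic respiration, amino acid synthesis and uptake, iron, fatty acids, nucleotides, sulfur, nitrogen, efflux and lac-driven expression. For none of these lists does that exclude a gene that was higher or less than 2 times lower with ethanol. Of the 43 genes, 28 were in no fixed list. Among these, bhsA, an outer membrane protein linked to resistance to several stresses, was 2.41 times lower (2.08 to 2.80). The uncharacterised genes ybiJ and yiiS were 2.39 (2.03 to 2.84) and 2.34 times lower (2.14 to 2.55). The inner membrane protein gene yeiH was 2.21 times lower (2.00 to 2.44).

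**Figure D2:**
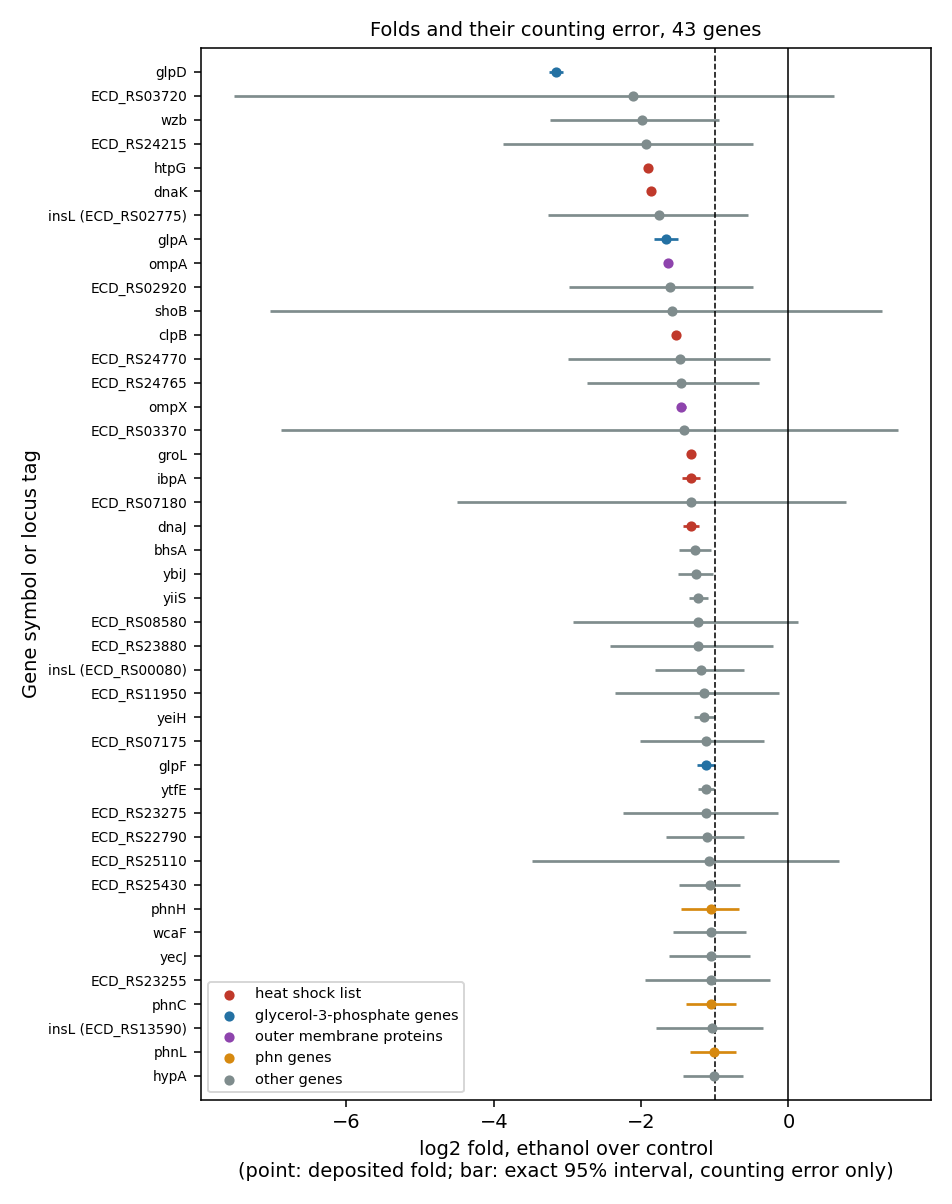
Log2 fold of ethanol over control for the 43 genes classed as lower, ordered by size, with symbols or locus tags on the vertical axis. Points are the deposited folds, bars are exact 95% intervals for counting error, and the dashed and solid vertical lines mark log2 folds of -1 and 0; bars are wide where the ethanol library held few reads, and 6 reach 0.

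In the authors' deposited table, unadjusted p-values of the 43 genes ran from 0.0245 to 0.869, and 4 genes were below 0.05, namely wzb, ybiJ, bhsA and glpA. The adjusted p was 1 for every one of the 64 genes in the authors' deposited tables used here. No gene of the heat shock list was among the 4, and in the authors' deposited table groL had an unadjusted p of 0.869 and dnaK one of 0.815. With 1 library per condition these p-values rest on no spread between replicates. They therefore do not rank the genes by support for a difference between conditions. The gene wzb, chosen after its values were seen, had 95 reads in the control and 8 with ethanol, 3.96 times lower (1.93 to 9.43).

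**Figure D3:**
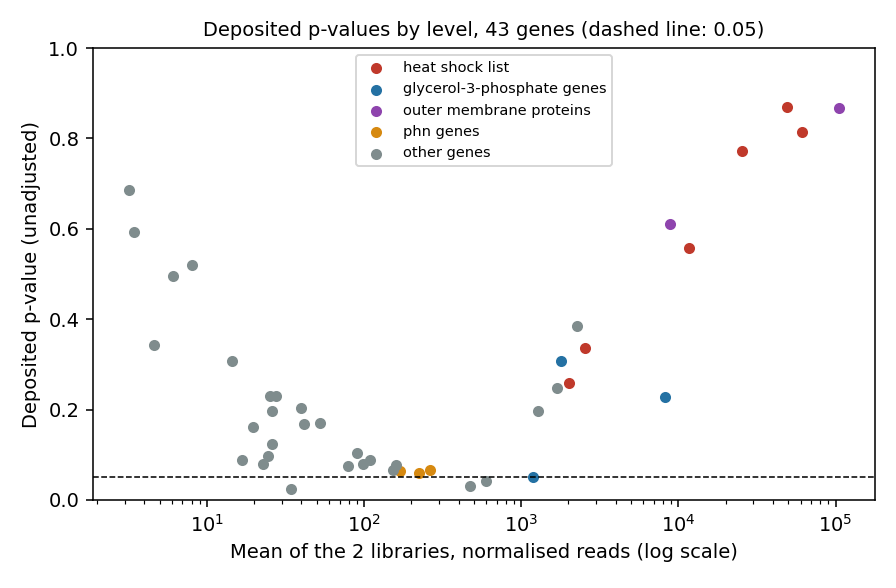
Unadjusted p-value from the authors' deposited table (vertical) against the mean normalised reads of both libraries (horizontal, log scale) for the 43 genes, 1 point per gene, with a dashed line at 0.05. The 7 genes with a mean above 5000 have p-values from 0.229 to 0.869, and the 9 genes with a mean from 100 to 1200 have p-values from 0.0319 to 0.0876. Over all 43 genes the Spearman correlation of p with mean level is 0.161.

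Genes listed for 1 library alone rested on very few reads. Of the 19 genes listed for the control library, 9 were tRNA genes and 10 coded for proteins. The highest was thiS, a sulfur carrier in thiamine synthesis, with 9 reads (level 5.20), followed by ECD_RS23735 with 7 reads and the tRNA-Val gene ECD_RS08585 with 5. The tRNA-Tyr gene ECD_RS06435 and the hypothetical protein genes ECD_RS23015 and ECD_RS25085 had 4 reads each, and 8 of the 19 genes had 1 read. A count of 0 in the ethanol library allows up to 3 reads, a level of 5.20, so absence from that library was not detectable at this depth for any of the 19. In the ethanol library alone, ymcF, annotated as a cold shock protein, had 2 reads and ECD_RS25320 had 1. For 0 of these 21 genes did the counting interval of the fold exclude no change.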

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

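Alternatives chosen after seeing the data were a size factor ratio of ethanol over control 10% lower and intervals excluding no change. So were 1 row for IS186, and no tRNA or hypothetical genes. Scaling to the total of the 43 listed genes raised every log2 fold by 1.63 and left 1 gene at 2 times lower or beyond, with 0 heat shock and 0 phosphate starvation genes. The cause lies in the construction, since the listed genes were selected for being lower, so this scaling bounds little. Under it 13 of the 18 named genes changed direction, with log2 folds of 0.10 for clpB, 0.18 for ompX, 0.31 for groL, ibpA and dnaJ, 0.36 for bhsA, 0.37 for ybiJ, 0.41 for yiiS, 0.49 for yeiH, 0.51 for glpF, 0.58 for phnH, 0.59 for phnC and 0.62 for phnL. A threshold of -2 left 2 genes, glpD and ECD_RS03720, with 0 heat shock and 0 phosphate starvation genes. Of these, ECD_RS03720 rested on 13 reads in the control and 1 with ethanol, and its counting interval reached no change. A pseudocount of 10 left 22 genes and 0 phosphate starvation genes, because it shrinks folds of low genes. Intervals beyond the threshold left 16 genes and 0 phosphate starvation genes. The size factor ratio of ethanol over control 10% lower raised every log2 fold by 0.15. It left 26 genes beyond the threshold and 0 phosphate starvation genes. Counting 1 gene per run of neighbours left 1 phosphate starvation gene. A minimum value of 10 left 0 of the 21 genes listed for 1 library. The count of lower genes was 29 to 42 with minimum values of 10 and 50, a pseudocount of 1, intervals excluding no change, 1 row for IS186, and no tRNA or hypothetical genes. The last pair was not run for the gene groups. Heat shock genes numbered 6, or 5 with 1 gene per run, under the alternatives run for them other than the total of the 43 and the threshold of -2. Phosphate starvation genes numbered 3 with either minimum value, a pseudocount of 1, intervals excluding no change, and the genes listed for the control library added. With pseudocounts of 1 and 10, log2 folds of the 18 named genes moved by at most 0.0067 and 0.063. Depth limits the lowest genes, of which 15 had 10 or fewer ethanol reads. No paired analysis was possible because each condition has 1 library.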

Other observations

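All tests of explanations given here were chosen after the results were seen. The genes wzb, wcaF, ytfE, insL and ECD_RS03720 were likewise chosen after their values were seen. Genes that GlpR, the glycerol-3-phosphate repressor, controls in E. coli number 9 in a list drawn up afterwards, and 3 of them (glpD, glpA and glpF) were among the 43 lower genes while 6 were not. A pair of genes for colanic acid, an exopolysaccharide of the envelope, was also listed. These were wzb, at 3.96 times lower (1.93 to 9.43, 8 reads with ethanol), and wcaF, at 2.07 times lower (1.49 to 2.96, 41 reads), which lie 7 genes apart in E. coli K-12. The gene ytfE, for repair of iron-sulfur clusters, was 2.17 times lower (2.02 to 2.34), with a level of 3115 in the control library and 1434 in the ethanol library. It was the only gene outside the rule for named genes whose interval lay wholly beyond 2 times lower.

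The insertion element IS186 was listed through 3 copies of its transposase gene insL, at 3.39 (1.47 to 9.59), 2.27 (1.52 to 3.51) and 2.05 times lower (1.27 to 3.47). Reads of the copies cannot be assigned with certainty. The copy with the highest level, 110.3 in the control, follows dnaJ in locus tag order. A prophage gene, the excisionase gene ECD_RS03720, had 13 reads in the control and 1 with ethanol, and its interval reached no change.

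Ethanol is a textbook inducer of the heat shock response in E. coli, whereas 6 heat shock chaperone genes were lower here in the ethanol library. Both libraries were taken 2 h after induction from cultures that produced an antibody fragment. An earlier response, or one in cells without the fragment, was not measured. A wrong library scaling is 1 common factor that leaves the order of the genes as it is. It therefore does not bear on the place of the 6 genes below the 4338 genes not classed as lower. That place rests on the authors' classes, since folds of those 4338 genes were not analysed here. All of the 43 lower genes share it by definition, so it lends no support to the heat shock genes in particular. Scaling bears on whether the amount of the 6 transcripts per cell was lower, which was not tested. A difference between cultures unrelated to ethanol cannot be told apart from an effect of ethanol with 1 library per condition, and an exchange of both labels was not tested. Compression of abundant transcripts may contribute and stays open. Heat shock genes make up 4 of the 7 most abundant of the 43 genes, but a rank among the 43 gives no rank among all genes. Of the 54 ribosomal protein genes, 0 were among the 43. The tables used here hold levels for 0 of them, so whether equally abundant transcripts were spared was not seen. Of the 15 pairs of heat shock genes, the more abundant gene had the larger fold with separate intervals in 8 and the less abundant gene in 3, and in 4 the intervals overlapped. All pairs are drawn from the same 6 genes and are not independent, so these counts cannot decide for or against compression.

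In the authors' deposited table, p was 0.05 or more for 33 of the 37 genes whose counting interval excluded no change. The dispersion that gives back each deposited p in a negative binomial test could be solved for 37 of the 43 genes. It was 0.103 at the lowest mean level solved (6.06), 0.0436 at a mean of 159.3, where it was lowest, and 0.544 for ompA at 105914. These dispersions are computed from the p-values themselves and so test no explanation of them, and no biological explanation was tested.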
